A study of Danio rerio with 20 samples.

How the data were processed

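Gene expression was measured in whole zebrafish (Danio rerio) larvae exposed for 96 h to nitroguanidine (NQ), an ingredient of insensitive munitions and propellants, after the solutions had been treated with ultraviolet light (UV-NQ). The labels give 4 groups: 6 control samples, 5 samples at 5.5 mg/L, 5 at 45.6 mg/L and 4 at 90.4 mg/L. These concentrations were measured before the ultraviolet treatment, so the amount of NQ left and of its photoproducts formed is not given in the sources used here. Per the labels' protocols, 8 larvae were held in each beaker of 250 ml without renewal of the solution, and the beakers were the exposure replicates. RNA was pooled from 4 whole fish per replicate, only RNA with an integrity number above 7.0 was accepted, and 600 ng of total RNA was labelled with Cy3. The design text describes the 4 h ultraviolet step for stocks of another munition mixture, and whether the control water passed through the same step is not given in the sources used here. The time of day at which the fish were collected is not given there either.

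Each sample was hybridised to its own array. Per the file headers, the authors scanned the arrays with Agilent Feature Extraction 10.7.3.1, and the deposited intensity values comprise the mean and local background intensity of each spot and a processed intensity that is background-subtracted, spatially detrended within the array and set to a surrogate value for dim spots. No normalization between arrays is contained in that column. The authors' deposited value table holds log2 values with the scale unstated. Compared with the scanner values, they were log2 processed intensities minus the 75th percentile of the array and then centred on the median of the 20 arrays for each probe, with median absolute differences of up to 0.00248 and column medians from -0.1212 to 0.1144. The direction is that of the scanner signal, and no part of the scale or the centring stayed unknown to within that difference.

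Each array carried 62976 spots, of which 1319 were controls and were left out. Spots of the same probe were averaged, which gave 43603 probes. Probe names in the files were those of the array design, annotated on the Zv9 (danRer7) assembly. Of the probes, 25724 matched a RefSeq gene table of assembly GRCz12tu by accession, 4313 by symbol and 1146 by synonym, and 12420 kept the name in the files. In all, 8354 probes received a name other than that in the files. That table was used for names alone, and all positions given are the Zv9 positions of the probes in the files. No genome sequence was used here, so exon, intron and untranslated region are not stated.

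The processed intensity was taken to log2 and the 75th percentile of the array over all probes other than controls was subtracted. Probes well above background on at least 4 arrays were kept (35659 probes). For each gene name the probe with the highest mean over the 20 arrays was used, which left 21122 features, 13258 of them with a gene symbol. Probes without a gene name were kept as themselves, so that 1 transcript can be counted under several names, and counts of changed features are not counts of genes. Where all arrays of a group lay below the background limit, the fold was given as a bound. The bound set the mean of the brighter group over all its arrays against the mean of, per array, the higher of the lowest signal well above background and the probe's own value.

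All 20 arrays were fitted together in 1 group-means model with limma 3.58.1 (lmFit and eBayes, without trend or robust options) in R 4.3.3, with the data.table package, version 1.17.8, and jsonlite 2.0.0. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 drew the plots and summaries. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 21122 features, and a feature was called at an adjusted p under 0.05. Every adjusted p given for a gene is from this model. The comparisons were each concentration with control, neighbouring concentrations with each other, and a slope on log2 of the concentration in mg/L plus 1.

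Sets of genes were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over 37 lists of pathway, tissue and cell type genes with at least 5 measured members. The lists held 1319 different genes, of which 1165 were measured. camera compares the members of a list with all other features, so a shift is relative to the other features. Where a list passed, its median and mean had the sign of the test, which did not hold for some lists that did not pass. The same test with the correlation estimated from the arrays is given beside the lists described as shifted, and with it no list passed an adjusted p of 0.05 in any comparison. Samples, comparisons, gene lists, the rule for named genes and all but 3 of the processing alternatives were fixed before the data were examined.

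The rule named, for each comparison with control, up to 10 genes with the largest rise and 10 with the largest fall among called features with a gene symbol that were well above background on every array of the brighter group and lay on 1 side of the control mean on every exposed array. Where fewer than 5 passed in a direction, the 5 with the smallest p were named as not passing. For each list the 4 members with the smallest p at 90.4 mg/L were named, and for the trend the 5 steepest slopes each way. Features outside this rule are marked as chosen after their values were seen.

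The test was checked on simulated data built on these arrays, with 200 of 21122 features changed. Of features changed 2-fold it recovered 61.2% at 5.5 mg/L, 55.2% at 45.6 mg/L, 53.7% at 90.4 mg/L and 65.7% for the trend. Of features changed 1.5-fold it recovered 14.9%, 13.4%, 7.5% and 16.4% in the same order, and of those changed 4-fold 92.4%, 93.9%, 89.4% and 92.4%. False calls numbered 7, 1, 6 and 8. Only the mean and SD of each feature came from the real arrays. The noise was independent between features and arrays, without effects of slide or row, so these false calls do not cover such structure.

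The arrays lay on 4 slides, named A to D here, in array row 1 or 2 of the slide. Slide B held no control array. Slide as a fixed and as a random block, slide with array row, and values within slides were computed. The other alternatives were normexp background correction with an offset of 50, quantile and median scaling, the authors' deposited log2 values, no filter, a filter at all 20 arrays and every probe on its own. In the model they were the replicate number as a block, only the groups compared, a trended and robust variance model, array weights, a 2-fold limit, linear and ranked concentration, and leaving out each array in turn. The 3 chosen after the data were seen left out 2 arrays that lay far out on the first principal component, left out 7 arrays on which repeated spots of a probe varied by over 10%, and took array row alone as a block.

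Comparisons with control share the 6 control arrays. Correlations between them are therefore given with the value from 100 simulations and with the real controls split 3 and 3. In the simulations unchanged groups shared simulated controls, with noise independent between features. The number of arrays limits the precision of every value. The labels describe the replicates as separate exposure replicates of pooled fish, and the p-values measure the spread between these pools.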

Results

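Larvae at 3 concentrations of UV-NQ were compared with control larvae on 20 single-colour arrays. The study's title asks about the raised toxicity of ultraviolet-degraded nitroguanidine and oxidative stress. Between 68.6% and 80.1% of probes were well above background on an array. The 75th percentile of the signal lay between 356 and 691, and no spot was saturated. Correlations between arrays across features ran from 0.9315 to 0.9832. The first principal component held 19.9% of the variance and the second 17.4%. Replicate 3 at 45.6 mg/L and replicate 2 at 5.5 mg/L lay at -94.51 and -63.67 on the first component, against values from -32.18 to 39.89 for the other arrays. The 5 arrays at 5.5 mg/L all lay in array row 2, and 3 of the 4 at 90.4 mg/L lay in row 1.

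Against control, 15 features differed at 5.5 mg/L, 5 at 45.6 mg/L and 1022 at 90.4 mg/L, of 21122 tested. At an unadjusted p under 0.05 the counts were 1640, 1991 and 4707. The direct comparison of 90.4 with 45.6 mg/L called 1 feature. The median standard error of a log2 difference was 0.217, 0.217 and 0.232 in the same order.

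At 5.5 mg/L, 3 features were higher and 12 lower than in control, and 4 of the 8 with a gene symbol belonged to the circadian clock list. nfil3-5, a repressor of the bZIP family tied to the clock, rose by 1.64 ± 0.21 on the log2 scale (SE, n = 5 against 6, adjusted p = 0.00307, limma; chromosome 6, 9616264 to 9616323). bmal1a, a transcription factor at the core of the clock, rose by 0.74 ± 0.10 (adjusted p = 0.00461; chromosome 25, 18381262 to 18381321). nr1d2b, a Rev-erb repressor, fell by 1.06 ± 0.15 (adjusted p = 0.00462; chromosome 19, 19395257 to 19395316). dbpa, a PAR bZIP factor driven by the clock, fell by 1.19 ± 0.22 (adjusted p = 0.0451; chromosome 19, 10798797 to 10798856). The cone photoreceptor arrestin arr3a fell by 1.196 ± 0.17 (adjusted p = 0.00461; chromosome 10, 27446784 to 27446843). The calcium-binding protein gene cabp5b fell by 1.16 ± 0.19 (adjusted p = 0.021). The receptor gene gpr55a fell by 1.34 ± 0.23 (adjusted p = 0.021) and crestin, a neural crest transcript, by 0.79 ± 0.15 (adjusted p = 0.0478). Each of the 8 lay on 1 side of the control mean on all 5 exposed arrays. The third higher feature, LOC793584, chosen after its values were seen, was at least 3.28-fold higher (adjusted p = 0.00876), with 0 of 6 control arrays above background. Of the genes that did not pass, scpp9 had a log2 difference of 2.69 (adjusted p = 0.0511), ihha of 0.63 (adjusted p = 0.0511) and hdc of 0.65 (adjusted p = 0.0634). With slide as a block 10 features were called, 9 of them among the 15, and with slide and array row 3. The calls of gpr55a, dbpa, cabp5b and crestin ended with slide as a block (adjusted p from 0.0715 to 0.125). Without replicate 2 at 5.5 mg/L the count was 28, without replicate 4 at 45.6 mg/L 26 and without control replicate 6 it was 9. The genes nfil3-5, bmal1a, arr3a and nr1d2b were called whichever array was left out.

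Among the gene lists at 5.5 mg/L, the 33 measured members of the circadian clock list held 2 higher and 2 lower, and 7 higher and 11 lower when adjusted over the list alone. Its median was -0.32 (camera adjusted p = 0.0423, and p = 0.391 with an estimated correlation). The phototransduction and photoreceptors list, with 50 measured, held 1 lower member over all features and 10 lower when adjusted over the list alone, with a median of -0.16 (adjusted p = 8.68e-05, and p = 0.127 with an estimated correlation). Other lists lay below the remaining features with no member called. Intestinal markers had a median of -0.37 (24 measured, adjusted p = 0.000204, and p = 0.168 with an estimated correlation). So lay cholesterol biosynthesis (25 measured, 21 below 0, adjusted p = 0.000204, and p = 0.159 with an estimated correlation) and exocrine pancreas and digestive enzymes (23 measured, 21 below 0, adjusted p = 0.000204, and p = 0.0764 with an estimated correlation). Of 50 oxidative phosphorylation genes 38 lay below 0 (adjusted p = 0.000797, and p = 0.301 with an estimated correlation). Of 100 splits of the same arrays, 45 gave as many lists as the 11 called here, and splits other than the real one called a median of 10. In all, 11 of 37 lists passed, 10 of them downward. The others were AhR and xenobiotic metabolism (adjusted p = 0.0142), fatty acid oxidation (0.0176), ribosome biogenesis (0.0221), skeletal muscle (0.0251) and, upward, estrogen response (0.0401). With an estimated correlation their p was 0.0295, 0.303, 0.523, 0.44 and 0.0283. With slide as a block the adjusted p was 0.0157 for the circadian clock list and 0.0026 for the photoreceptor list, and the fatty acid oxidation and estrogen response lists no longer passed (both adjusted p = 0.108). With array row as a block, chosen after the data were seen, the clock and ribosome biogenesis lists no longer passed (adjusted p = 0.249 and 0.263). With slide and row together the clock (0.106), ribosome biogenesis (0.147), cholesterol (0.0856) and oxidative phosphorylation lists (0.106) did not pass. The photoreceptor list's median relative to all features was -0.12, -0.07 and -0.25 within slides A, C and D. These slides held 2, 1 and 1 exposed arrays against 2, 3 and 1 control arrays. Within slide D the cholesterol (0.033), exocrine pancreas (0.181), fatty acid oxidation (0.098) and skeletal muscle lists (0.016) lay the other way, as did ribosome biogenesis within slides A and C (0.013 and 0.079). Of the 20 fits that left out 1 array, the clock list was called in 10, estrogen response in 13, ribosome biogenesis in 15, skeletal muscle in 16 and the photoreceptor, intestinal and cholesterol lists in 20. The AhR, exocrine pancreas and fatty acid oxidation lists lost the call without replicate 2 at 5.5 mg/L (medians -0.135, -0.052 and -0.029) and the oxidative phosphorylation list without control replicate 4 (-0.046).

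**Figure D1:**
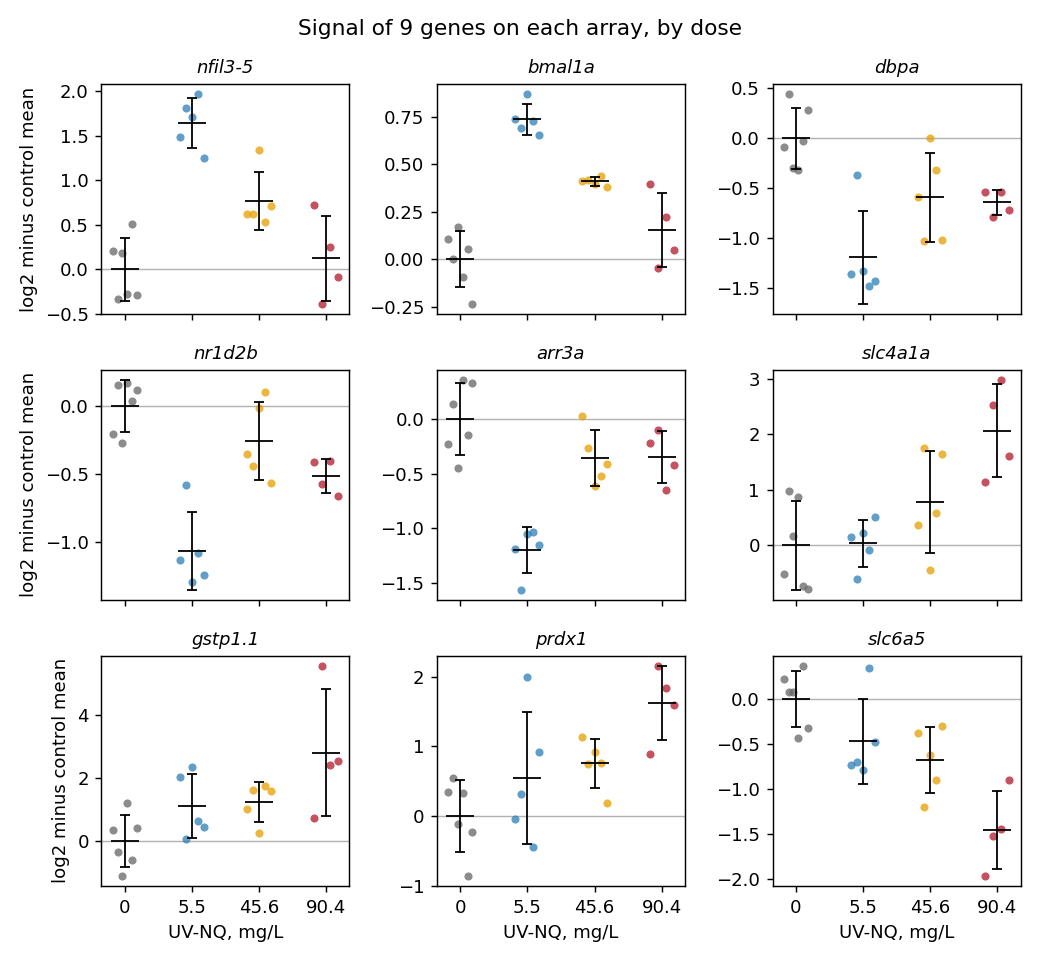
Log2 signal of 9 genes minus the control mean (vertical axis) in each array of the 4 groups (horizontal axis, mg/L UV-NQ), with the mean and SD of each group. nfil3-5 and bmal1a were highest at 5.5 mg/L, where they rose by 1.64 and 0.74, while slc4a1a, gstp1.1 and prdx1 were highest at 90.4 mg/L, where they rose by 2.06, 2.80 and 1.62.

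At 45.6 mg/L no feature was higher and 5 were lower, none with a gene symbol. All 5, chosen after their values were seen, are named by clone, transcript or probe. si:dkey-217m5.8 and NP13326950 had log2 differences of -1.99 and -3.104 (both adjusted p = 0.0111), and TC454255 and the probe A_15_P144896 of -1.71 and -2.93 (both adjusted p = 0.0376). A_15_P144896 was above background on 1 of 5 exposed arrays, so that its size rests on dim values. EH548857 was at least 12.2-fold lower, with 0 of 5 exposed arrays above background (adjusted p = 0.0289). At 90.4 mg/L, against the same controls, si:dkey-217m5.8, NP13326950 and A_15_P144896 were also called lower (-2.68, -3.26 and -3.53, adjusted p = 0.00054, 0.00339 and 0.00363). A_15_P144896 was above background there on 1 array. TC454255 and EH548857 did not pass there (-0.86 and 0.097, adjusted p = 0.0958 and 0.96). At 5.5 mg/L NP13326950 was called as well (-2.51, adjusted p = 0.0306). The genes nearest to passing lay above the control mean in all 5 exposed arrays (n = 5 against 6 in the limma fit). cfap52, of motile cilia, was at 1.19 ± 0.22 and pdk4, a kinase that restrains pyruvate oxidation, at 0.94 ± 0.17 (both adjusted p = 0.0534). The mitochondrial carrier gene slc25a44a was at 0.74 ± 0.14 (adjusted p = 0.0588), the glutathione transferase gene mgst2 at 0.79 ± 0.15 (adjusted p = 0.0682) and b4galt1 at 0.66 ± 0.13 (adjusted p = 0.0719). No call was left with slide as a block. All 5 features were lower within slides A and D, which their choice on the same arrays largely fixes. The count was 18 without control replicate 4, 15 without replicate 2 at 5.5 mg/L, 10 without replicate 1 at 90.4 mg/L and 8 without replicate 5 at 5.5 mg/L. It was 3 without control replicate 1, without replicates 1 or 4 at 5.5 mg/L or without replicate 3 at 45.6 mg/L, and 2 without control replicates 2 or 6.

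Of the lists, 4 lay higher and 4 lower at 45.6 mg/L, with no member called, and 87 of 100 splits of the same arrays gave as many. Splits other than the real one called a median of 15 lists. The erythroid and heme list had a median of 0.37 (31 measured, 3 higher when adjusted over the list alone, adjusted p = 0.000365, and p = 0.149 with an estimated correlation). Its mean was 1.503 on replicate 5 against 0.14 to 0.44 on the others. The glucocorticoid response list had a median of 0.35 (25 measured, 4 higher when adjusted over the list alone, adjusted p = 0.000211, and p = 0.0379 with an estimated correlation, which did not pass adjustment at 0.811). The immediate early genes had one of 0.27 (32 measured, 2 higher and 1 lower when adjusted over the list alone, adjusted p = 0.000871, and p = 0.166 with an estimated correlation). In the ribosome biogenesis list 43 of 47 members lay above 0 (adjusted p = 4.97e-05, and p = 0.28 with an estimated correlation). In the skeletal muscle list 42 of 48 lay below 0 (adjusted p = 0.000189, and p = 0.221 with an estimated correlation). The cholesterol biosynthesis (adjusted p = 0.00683), cell cycle and DNA replication (adjusted p = 0.0117) and collagen, cartilage and bone lists (adjusted p = 0.0191) lay lower. With an estimated correlation their p was 0.277, 0.508 and 0.479. The cholesterol and cell cycle lists no longer passed with slide as a block (adjusted p = 0.333 and 0.669). Without replicate 3, which lay far out on the first component, the calls of the ribosome biogenesis, skeletal muscle, immediate early, cholesterol, cell cycle and collagen lists ended, with medians of 0.06, -0.11, 0.12, -0.20, 0.003 and 0.058. The calls of the cholesterol, cell cycle and collagen lists also ended without control replicates 2 or 4 or replicate 4 at 45.6 mg/L, and those of the last 2 without control replicate 3. Within slide D, with 2 exposed arrays against 1 control array, these 3 lists lay the other way, at 0.083, 0.249 and 0.289 relative to all features. Within slide A the immediate early list lay the other way (-0.052). The other shifted lists kept their direction there, with ribosome biogenesis at 0.05. The erythroid list kept its call without replicate 5, at a median of 0.25 and an adjusted p of 0.0441.

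At 90.4 mg/L, 249 features were higher and 773 lower, 502 of them by at least 2-fold (98 higher and 404 lower). Among the named genes gstp1.1, a glutathione S-transferase, rose by 2.80 ± 0.69 on the log2 scale (SE, n = 4 against 6, adjusted p = 0.0293, limma; chromosome 4, 29628060 to 29628119). Its 4 exposed arrays lay at 0.73, 5.53, 2.42 and 2.53, and without replicate 2 the difference was 1.89 and did not pass (adjusted p = 0.107). Among membrane transporters, slc4a1a, the anion exchanger of red blood cells, rose by 2.06 ± 0.46 (adjusted p = 0.021; chromosome 3, 19955787 to 19955986). slc22a6l, of the organic anion transporter family, rose by 2.02 ± 0.29 (adjusted p = 0.00339; chromosome 21, 27887872 to 27887931) and the epithelial calcium channel gene trpv6 by 2.01 ± 0.43 (adjusted p = 0.0181; chromosome 16, 14044375 to 14044432). The lectin genes jac9 and jac6, whose probes lie side by side on chromosome 7, rose by 1.92 ± 0.35 and 1.73 ± 0.45 (adjusted p = 0.00809 and 0.0346), and rfesd, fitm1 and tmem26b by 2.11, 1.77 and 1.70. The helicase gene ddx43 was at least 3.78-fold higher (adjusted p = 0.0451), with 0 of 6 control arrays and 4 of 4 exposed arrays above background. dmrt1, a transcription factor of testis development, had the largest fall among called genes with a symbol that the rule allowed and fell by 3.21 ± 0.76 (adjusted p = 0.0263; chromosome 5, 46564796 to 46564855). Genes of interferon-induced families fell by 2.38 ± 0.48 (ifit15, adjusted p = 0.0143) and 1.97 ± 0.46 (ifi44f4, adjusted p = 0.0241). The trim family genes btr32 and ftr61 fell by 2.29 ± 0.41 and 1.84 ± 0.43 (adjusted p = 0.00785 and 0.0249) and the caspase gene casp6b.2 by 2.08 ± 0.59 (adjusted p = 0.048). pimr128, ppef1, slitrk4 and ugt1b7 had log2 differences of -2.34, -1.87, -1.81 and -1.70. The second probe of pimr128 lay on the other side of 0. These 20 genes lay on 1 side of the control mean on all 4 exposed arrays. At 90.4 mg/L dmrt1 and ppef1 were above background on 2 of 4 arrays and pimr128 and ftr61 on 3.

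The count at 90.4 mg/L and the split between higher and lower calls moved with the processing. With slide as a block 461 features were called, 418 of them among the 1022, and with slide and array row 324. The calls of rfesd, jac6, tmem26b, pimr128, casp6b.2, ifi44f4 and ftr61 ended with slide as a block (adjusted p from 0.0514 to 0.151). Of the 1022 features, 1021 had the same sign within slide C and 1022 within slide D, which their calling on the same arrays largely fixes. Median scaling of the arrays gave 467 higher and 428 lower (47.8% lower, against 75.6%) and quantile scaling 255 and 426 (62.6%). Of calls of at least 2-fold 62.7% were lower with median scaling, against 80.5%. The 98 higher and 404 lower such calls became 51 and 103 with normexp background correction, 111 and 216 with quantile scaling and 65 and 260 with slide as a block. They became 16 and 89 without replicate 4 at 90.4 mg/L, 21 and 105 without replicate 2 and 47 and 231 without replicate 3. They became 58 and 198, 51 and 202, 142 and 692, 48 and 155 and 45 and 228 without control replicates 1, 3, 4, 5 and 6. The median of all features moved from -0.056 to 0.064 with median scaling. Leaving out 1 array gave 137 (replicate 4 at 90.4 mg/L), 161 (replicate 2), 400 (replicate 3) and 646 (replicate 1). The counts were 406, 412, 1812, 325 and 418 without control replicates 1, 3, 4, 5 and 6. Of the 20 genes above, slc22a6l, jac9, btr32, ppef1, slitrk4 and ugt1b7 were called whichever array was left out. Of the others, 14 lost the call without replicate 4 at 90.4 mg/L and 13 without replicate 2. On replicate 4, 68.7% of probes were well above background, against 79.2% to 80.1% on the other 3. Replicate 4 was the only array of its group in array row 2, where arrays of the other groups ran from 68.6% to 77.2%.

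Some erythroid and antioxidant genes rose at 90.4 mg/L, and most members of both lists did not pass. Of 31 measured members of the erythroid and heme list 8 were higher and none was lower over all features. When adjusted over the list alone, 15 were higher. The list's median was 0.80 (adjusted p = 3.61e-11, and p = 0.018 with an estimated correlation, adjusted p = 0.536). Besides slc4a1a, the embryonic globin genes hbbe1.1 and hbae3 rose by 1.04 ± 0.18 (adjusted p = 0.00785) and 1.01 ± 0.22 (adjusted p = 0.0194). blvrb, which encodes biliverdin reductase B, rose by 0.94 ± 0.17 (adjusted p = 0.00875). Relative to all features the median of the list was 1.17 within slide C (replicate 2 against control replicates 1, 4 and 5). It was 1.39 within slide D (replicates 3 and 4 against control replicate 6). Each of these rests on a single array on 1 side. Of 42 members of the Nrf2 and antioxidant list 4 were higher and 1 lower, the same counts as when adjusted over the list alone. The median was 0.27 (adjusted p = 0.00016, and p = 0.0355 with an estimated correlation, which did not pass adjustment at 0.536). Besides gstp1.1, the peroxiredoxin gene prdx1 rose by 1.62 ± 0.38 (adjusted p = 0.025) and the thioredoxin reductase gene txnrd3 by 0.77 ± 0.15 (adjusted p = 0.0103). srxn1, the gene of sulfiredoxin, fell by 0.78 ± 0.21 (adjusted p = 0.0372). With slide as a block the adjusted p was 3.84e-11 for the erythroid and heme list and 0.000787 for the Nrf2 and antioxidant list. prdx1 and srxn1 no longer passed under that block (adjusted p = 0.0748 and 0.0562). The median of the Nrf2 and antioxidant list relative to all features was 0.30 within slide C and 0.38 within slide D, from the same few arrays. Both lists were called in all 20 fits that left out 1 array, but without replicate 4 at 90.4 mg/L prdx1, gstp1.1, srxn1, hbae3 and slc4a1a no longer passed.

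Of 48 measured members of the neuronal and synaptic list 5 were lower at 90.4 mg/L, 43 did not pass and none was higher, also when adjusted over the list alone. They included slc6a5, the glycine transporter of inhibitory neurons, which fell by 1.45 ± 0.25 (adjusted p = 0.0078). The glutamate receptor genes gria2a and grin1b fell by 1.11 ± 0.21 (adjusted p = 0.00978) and 1.02 ± 0.25 (adjusted p = 0.0314), and the sodium channel gene scn8aa fell by 0.98 ± 0.21 (adjusted p = 0.0175). The list as a whole had a median of -0.17 (adjusted p = 0.0481, and p = 0.375 with an estimated correlation) and did not pass with slide (adjusted p = 0.0677) or array row (0.15) as a block or in 10 of the 20 fits that left out 1 array. These were the fits without control replicates 1, 3, 5 or 6 or without replicates 2 or 3 at any of the 3 concentrations. The median was -0.12 without replicate 3 at 90.4 mg/L and -0.15 without replicate 2. slc6a5 was called in all 37 alternatives, and grin1b was not called with slide as a block (adjusted p = 0.0535). gria2a, scn8aa and grin1b were not called without replicate 4 at 90.4 mg/L.

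Some genes of energy metabolism changed at 90.4 mg/L. The gluconeogenesis and glucose list, with 29 measured, held 2 higher and 1 lower, and 4 higher and 1 lower when adjusted over the list alone. The gluconeogenic genes pck1 and g6pc1a.2 rose by 1.33 ± 0.29 (adjusted p = 0.019) and 1.25 ± 0.23 (adjusted p = 0.00875), and the glucokinase gene gck fell by 1.51 ± 0.28 (adjusted p = 0.00875). The fatty acid oxidation and PPAR list, with 33 measured, held 2 higher and 1 lower. pdk4 rose by 1.12 ± 0.18 (adjusted p = 0.00671) and pdk2b by 1.01 ± 0.26 (adjusted p = 0.0346). etfa, of the electron transfer flavoprotein, fell by 1.04 ± 0.26 (adjusted p = 0.0308). Both lists lay above the remaining features, at adjusted p = 0.0449 and 0.0234 (p = 0.285 and 0.348 with an estimated correlation). In the cholesterol biosynthesis list 21 of 25 members lay above 0, with the regulator srebf2 higher by 0.92 ± 0.25 (adjusted p = 0.043). The median was 0.53 (adjusted p = 0.00202, and p = 0.238 with an estimated correlation). The calls of pdk2b, etfa and srebf2 were lost with slide as a block (adjusted p = 0.0666, 0.0885 and 0.0875) and that of pck1 without replicates 2 or 4 at 90.4 mg/L. Of 37 called members named for all lists, 30 lost the call without replicate 4, 28 without replicate 2, 20 without replicate 3 and 17, 14, 19 and 16 without control replicates 1, 3, 5 and 6. The members called whichever array was left out were txnrd3, pdk4, g6pc1a.2, gck, hbbe1.1, blvrb and slc6a5. Without replicate 2 at 90.4 mg/L these 3 lists no longer passed, with medians of 0.12, 0.25 and 0.24. The call of the gluconeogenesis list also ended without replicates 3 or 4 there (0.13 and 0.17) and without control replicates 3, 4 or 6 (0.16, 0.18 and 0.17).

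Ribosomal lists passed at the preset correlation but not with an estimated one, with hardly a call among their members. Of 66 ribosomal protein genes 63 lay below 0 at 90.4 mg/L and none was called (median -0.19, adjusted p = 0.00016, and p = 0.336 with an estimated correlation). Their median was -0.07 with median scaling and -0.01 with quantile scaling, where the ribosomal proteins list did not pass (adjusted p = 0.571). Of 47 ribosome biogenesis genes 37 lay above 0 (median 0.19, adjusted p = 0.000154, and p = 0.317 with an estimated correlation). The called member was gar1, a component of the snoRNPs that modify ribosomal RNA, which rose by 0.71 ± 0.17. The complement and acute phase list lay higher (35 measured, 29 above 0, median 0.30, adjusted p = 0.000414, and p = 0.19 with an estimated correlation). So did the oxidative phosphorylation list (50 measured, 38 above 0, adjusted p = 0.00193, and p = 0.335 with an estimated correlation), with ndufa9a as the called member (0.55 ± 0.14, adjusted p = 0.0377, and 0.0855 with slide as a block). In the circadian clock list 29 of 33 members lay below 0 and none was called by its brightest probe (median -0.32, adjusted p = 0.00814, and p = 0.285 with an estimated correlation). nr1d2b was at -0.51 ± 0.16 (adjusted p = 0.0693), and of its 3 probes, all lower, 1 was called when every probe was tested. Neutrophil and macrophage markers (median 0.20, adjusted p = 0.0197), intestinal markers (0.21, 0.0234), the cell cycle list (0.19, 0.0234) and cardiac markers (0.18, 0.0481) lay higher with no member called. With an estimated correlation their p was 0.182, 0.378, 0.56 and 0.212, and the cardiac markers did not pass with slide as a block (adjusted p = 0.0754). Without replicate 2 at 90.4 mg/L the neutrophil (0.12), intestinal (0.17) and cell cycle lists (0.07) did not pass, and the cardiac markers passed in 9 of the 20 fits that left out 1 array. The neutrophil list also failed without replicate 3 (0.24), the intestinal list without replicate 4 (0.18), and the cell cycle list without replicate 4 (0.14) and control replicates 5 and 6 (0.08 and 0.12). In all, 16 lists lay higher and 3 lower, and 2 of 100 splits of the same arrays gave as many. Splits other than the real one called a median of 9 lists. With slide as a block the adjusted p was 6.03e-07 for ribosomal proteins, 0.000354 for ribosome biogenesis, 0.000118 for complement, 0.000855 for oxidative phosphorylation and 0.00115 for the clock list. The clock list did not pass without replicate 2 at 90.4 mg/L (median -0.22).

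**Figure D2:**
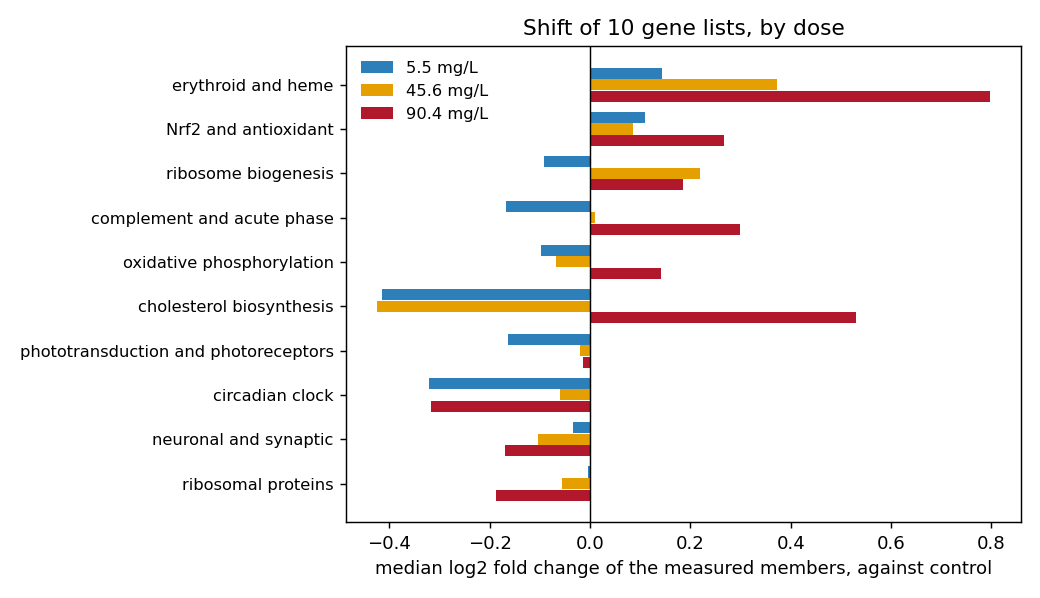
Median log2 difference from control (horizontal axis) over the measured members of 10 gene lists (vertical axis), with bars coloured by the 3 concentrations of UV-NQ (mg/L). The erythroid and heme list reached 0.80 at 90.4 mg/L, and the cholesterol biosynthesis list lay below 0 at both lower concentrations and at 0.53 at the highest.

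The slope over all concentrations was called for 596 features, 198 rising and 398 falling. Of these, 499 were also called at 90.4 mg/L in the same direction. Among the rising genes named by the rule, the slope per doubling of the concentration plus 1 was highest for rfesd (0.28 ± 0.07, adjusted p = 0.0346), slc22a6l (0.28 ± 0.04, adjusted p = 0.00294), slc4a1a (0.26 ± 0.07, adjusted p = 0.0476) and the annexin gene anxa5a (0.23 ± 0.04, adjusted p = 0.012). ddx43 also passed (adjusted p = 0.0326), but with 0 of 6 control arrays above background its slope is not given. The steepest falls were those of dmrt1 (-0.39 ± 0.11, adjusted p = 0.0477), ifit15 (-0.36 ± 0.07, adjusted p = 0.012), casp6b.2 (-0.33 ± 0.08, adjusted p = 0.0276), the phosphatase gene ptpn18 (-0.28 ± 0.05, adjusted p = 0.0118) and btr32 (-0.26 ± 0.06, adjusted p = 0.0346). The slopes of rfesd, slc4a1a, ifit15, casp6b.2 and btr32 no longer passed with slide as a block (adjusted p from 0.0522 to 0.109). That block left 255 slopes called, and over the exposed arrays alone 371 were called. Median scaling gave 348 rising and 232 falling (quantile scaling 227 and 244). Leaving out 1 array gave 205, 147, 238 and 149 (replicates 1 to 4 at 90.4 mg/L) and 1074, 240, 910 and 923 (replicates 1 to 4 at 45.6 mg/L). It gave 219, 229, 1489, 184 and 195 without control replicates 1, 3, 4, 5 and 6. slc22a6l, anxa5a, ifit15 and ptpn18 were called in each of these fits.

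Neighbouring concentrations differed in 1 feature each. slc47a2.1, of the multidrug and toxin extrusion transporters, was higher at 45.6 than at 5.5 mg/L by 1.298 ± 0.18 (n = 5 against 5, adjusted p = 0.019, limma; chromosome 21, 38828603 to 38828662), with 1 of 5 arrays at 5.5 mg/L above background. LOC559843, chosen after its values were seen, was lower at 90.4 than at 45.6 mg/L by 1.72 ± 0.24 (n = 4 against 5, adjusted p = 0.0156, limma). Between 45.6 and 5.5 mg/L, nr1d2b, arr3a and nfil3-5 were at 0.81 ± 0.16, 0.84 ± 0.17 and -0.88 ± 0.22, none of which passed (adjusted p = 0.212, 0.322 and 0.559). Nor did atp1a1b (0.68), lpcat4 (0.94), gxylt1b (-0.92), hdc (-0.57), dock1 (-1.196) or ptprb (-1.15). Between 90.4 and 45.6 mg/L, ptprb (1.58), efhd1 (0.64), cel.2 (5.94), npsn (1.08), wnt10a (1.15), skor1a (-0.95), kctd8 (-1.12), prkag3 (-0.67), crybb3 (-0.95) and elmod1 (-1.29) did not pass, at adjusted p from 0.43 to 0.501. Probes of some of these genes differed in sign against control. The sign of the probe used was that of 1 of 3 cel.2 probes at 45.6 mg/L and 2 of 3 at 90.4 mg/L, itself counted. It was that of 4 of 6 npsn, 2 of 3 prkag3 and 1 of 2 crybb3 probes at 45.6 mg/L. For ptprb it was that of 1 of 2 probes at 90.4 mg/L, and at 5.5 mg/L that of 1 of 4 dock1 and 1 of 2 atp1a1b probes. At an unadjusted p under 0.05 the counts were 1484 and 1992. The call of slc47a2.1 ended with slide or array row as a block, with normexp background correction, with array weights, with only the groups compared and among features above background on all 20 arrays. It also ended without replicates 2, 3, 4 or 5 at 5.5 mg/L or replicates 1 or 2 at 45.6 mg/L, and without the 2 arrays far out on the first component (count 0). The count rose to 2 without replicate 4 at 45.6 mg/L and to 3 without replicate 5. The call of LOC559843 ended without replicates 1 or 4 at 45.6 mg/L or replicate 2 at 90.4 mg/L, without the 2 arrays far out on the first component and with slide and array row together as blocks (count 0). It also ended with only the groups compared and without the 7 arrays with variable repeated spots, where the 1 feature called was another and higher. Without those 7 arrays the 1 feature called between 45.6 and 5.5 mg/L was not slc47a2.1 either. The count rose to 2 without control replicate 4, replicate 1 at 5.5 mg/L or replicate 1 at 90.4 mg/L, and to 5 without replicate 2 at 45.6 mg/L.

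Across features, which are not independent replicates, Pearson's r was 0.623 between 45.6 and 90.4 mg/L (Spearman 0.58), 0.552 between 5.5 and 45.6 mg/L (0.483) and 0.328 between 5.5 and 90.4 mg/L (0.268). Simulated unchanged groups that shared simulated controls gave 0.427, 0.455 and 0.426 on average, and with the real controls split the medians were 0.405, 0.25 and 0.138. The covariance exceeded the simulated one by 0.0826, 0.0324 and 0.0186.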

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

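The tests of the clock genes, of the share of lower calls and of neighbouring calls with a gene symbol were chosen only after the results were seen, and the other tests before.

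In 118 comparisons within groups, 10 single values lay far from the rest of their group by Dixon's criterion, which chance alone gives in about 0.05 of groups. On replicate 4 at 90.4 mg/L 68.7% of probes were well above background, against 79.2% to 80.1% on the other 3 arrays. The mean of its negative controls was -7.57 against -4.09 to -3.38. It was the only array of its group in array row 2. Arrays of that row in the other groups ran from 68.6% to 77.2% and from -12.5 to -5.11, so both values lie within the range of the row. Repeated spots of a probe varied by 18.6% on replicate 4 at 45.6 mg/L, against 6.12% to 7.57% in its group, and by 13.4% on replicate 1 at 90.4 mg/L, against 5.8% to 6.55%. Relative to the control mean, gpr55a lay at -2.18 on replicate 1 at 5.5 mg/L, against -1.19 to -1.05 on the other arrays. On replicate 2 at 5.5 mg/L arr3a lay at -1.56, against -1.18 to -1.03, and dbpa at -0.37, against -1.48 to -1.33. jac6 lay at -1.55 on control replicate 2, against 0.07 to 0.45. The mean of the erythroid and heme list was 1.503 on replicate 5 at 45.6 mg/L, against 0.14 to 0.44. That of the ribosomal proteins list was -0.36 on replicate 2 at 90.4 mg/L, against -0.15 to -0.11. Between concentrations the difference itself passed for slc47a2.1 (1.298, 45.6 against 5.5 mg/L) and LOC559843 (-1.72, 90.4 against 45.6 mg/L).

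At 5.5 mg/L, 8 clock genes that textbooks place under ROR and Rev-erb control lay at a mean of 0.79 ± 0.19 (SD, n = 5) and 13 that they place under E-box control at -0.75 ± 0.51, so that the arms differed by 1.54 (two-sided exact permutation p = 0.00216, adjusted p = 0.0108). Array row as the whole cause is argued against, since the difference was 1.39 over row 2 alone (exact p = 0.0179, adjusted p = 0.0397). There 5 arrays stood against 3, and every exposed array lay above every control array. From 5.5 to 45.6 mg/L the difference between the arms changed by -0.97 (exact p = 0.0238, adjusted p = 0.0397). This met the bound set against a response that grows with concentration, but it cannot decide the question. The pattern was picked at 5.5 mg/L, which by itself favours a smaller value elsewhere, and array row also differed between these groups. Singly, bmal1a, nr1d2b, nfil3-5 and dbpa did not pass between these concentrations (limma, adjusted p from 0.212 to 0.657). The pattern may come from another time of day at collection or from an effect of the exposure on the clock, which cannot be told apart because both give a difference such as 1.54 and no collection time is given. On 4 of 5 arrays the E-box arm lay below the control mean and on replicate 2 it lay at 0.11; a first form of the test, under which 1 such array would have excluded the time of day, was replaced for that reason. Against control the difference between the arms was 0.56 at 45.6 mg/L (exact permutation p = 0.0455, adjusted p = 0.0568) and 0.39 at 90.4 mg/L (p = 0.11, adjusted p = 0.11). The 4 clock genes called were part of the arms, and the test was chosen after the results were seen. Neither the size nor the p-value of the difference is therefore independent of the choice. With 462 and 56 splits, 0.00216 and 0.0179 are also the lowest p possible.

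Of the calls at 90.4 mg/L, 75.6% were lower. For the share among all calls, array row and dim probes are argued against, since it was 75.6% with array row as a block and 72.2% among features above background on all 20 arrays. With median scaling it was 47.8%, but a shift of all features turns calls near the threshold by itself, and this value does not show that scaling made the excess. Among calls of at least 2-fold, 80.5% were lower, and 62.7% with median scaling, which lies between the bounds set for and against scaling. For these larger calls no bound was set for array row or dim probes, and both stay open there. Scaling and a general fall in the level of many transcripts with the exposure cannot be told apart, since an array scaled to itself shows neither.

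Of the 741 lower calls at 90.4 mg/L with a position, 194 had another within 100 kb, against a median of 110 and a highest value of 161 in 1000 random sets matched on mean level; of 242 higher calls 41 had one, against a median of 13 and a highest value of 30. Haplotypes or copy numbers that differ between pools of fish may give this, and 194 met the bound set for them beforehand, but 1 transcript under several names would give the same excess. Left with 1 call per name stem and chromosome, 171 calls had a neighbour (random sets up to 147), which by the bound set beforehand would exclude probes that read a shared gene family, but 426 of the calls have no gene symbol and so no stem, and the test cannot exclude it for them. Over the 315 calls with a gene symbol the number was 27, against a median of 20, a 95th percentile of 30 and a highest value of 40. These calls alone show no clear excess of neighbours. The value of 27 neither shows nor excludes that 1 transcript was tested under several names. The 3 explanations therefore cannot be told apart, and no genome sequence was at hand to map the probes.

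The same arrays were split 100 times, the real split included. By the bound of 0.05 set beforehand, chance is argued against for the genes at 5.5 mg/L (1 split with as many, real 15, highest other 0) and 90.4 mg/L (2 splits, real 1022, highest other 1402). The same holds for the trend (1 split, real 596, highest other 4) and for the lists at 90.4 mg/L (2 splits, real 19, highest other 20). These splits did not keep slides together, so they do not exclude a structure shared with the slides. At 90.4 mg/L the highest other split exceeded the real one for features and for lists, and with an estimated correlation 0 lists passed. Chance was not excluded for 45.6 against 5.5 mg/L (15 splits, real 1, highest other 1256), for 90.4 against 45.6 mg/L (6 splits, real 1, highest other 1022), or for the lists at 5.5 mg/L (45 splits, real 11, highest other 21) and 45.6 mg/L (87 splits, real 8, highest other 23). For the genes at 45.6 mg/L 4 splits gave as many (real 5, highest other 569), a share under 0.05, but the splits did not keep slides together. With slide as a block the counts were 10 at 5.5 mg/L, 0 at 45.6 mg/L and 461 at 90.4 mg/L, so chance is not set aside for the 5 features at 45.6 mg/L. The splits with 569, 1256, 1402 and 1022 calls show that groupings other than the real ones can give many calls. What sets the arrays of those splits apart was not tested.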

How the results depend on the processing

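The alternatives that left out 2 arrays far out on the first component, left out 7 arrays with variable repeated spots, or took array row alone as a block were chosen only after the data were seen; the others were planned. The cause of the changes was not tested except where fewer arrays or features entered. The authors' deposited values and the random slide block kept every count within 1.5 times of the one reported, and the random block was not run for the lists. The 208 results on named genes had 7666 alternative values, of which 6823 kept their direction and side of the threshold, 581 no longer passed, 261 newly passed and 1 reversed: psme1 at 90.4 mg/L, to 0.00049 without the 7 arrays.

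For 5.5 mg/L (15) the counts that moved were 25 with normexp, 33 with quantile scaling, 34 over features above background on all 20 arrays and 3 with slide and row. They were 29 with a trended robust variance, 142 with array weights, 60 without the 2 arrays and 1 without the 7, and 9 to 28 on leaving out 1 array. For 45.6 mg/L (5) they were 9 with normexp, 12 with quantile and 9 with median scaling, 0 on all 20 arrays, 0 with slide and 0 with slide and row. They were 9 with a trended robust variance, 32 with array weights, 3 with row and 3 without the 2 arrays, and 2 to 18 on leaving out 1 array. For 90.4 mg/L (1022) they were 681 with quantile scaling, 671 with no filter, 1754 over every probe, 461 with slide and 324 with slide and row. They were 1748 with only the groups compared, 5654 with array weights, 2139 without the 7 arrays and 502 at 2-fold, and 137 to 1812 on leaving out 1 array. For the trend (596) they were 365 with no filter, 1006 over every probe, 255 with slide, 142 with slide and row and 371 over the exposed arrays. They were 5414 with weights, 292 with row, 1045 without the 2 arrays, 1700 without the 7, 1899 with linear and 1194 with ranked concentration, and 147 to 1489 on leaving out 1 array.

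Between 45.6 and 5.5 mg/L the count of 1 went to 0 with normexp, all 20 arrays, slide, slide and row, only the groups compared, weights, row and without the 2 arrays, and to between 0 and 3 on leaving out 1 array. Between 90.4 and 45.6 mg/L it went to 2 with no filter, 0 with slide and row, 4 with weights and 0 without the 2 arrays, and to between 0 and 5 on leaving out 1 array. The lists called at 5.5 mg/L (11) went to 6 with quantile scaling, 20 without the 7 arrays, and 8 to 12 on leaving out 1 array. Those at 45.6 mg/L (8) went to 14 over every probe, 4 with weights and 6 to 15 on leaving out 1 array. Those at 90.4 mg/L (19) went to 8 with quantile and 12 with median scaling, 11 on all 20 arrays and 11 to 20. With an estimated correlation 0 lists were called at each concentration. The correlations between concentrations of 0.552, 0.328 and 0.623 went to 0.25, 0.138 and 0.405 with the controls split, and to 0.4 to 0.602, 0.268 to 0.421 and 0.483 to 0.684 on leaving out 1 array.

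The replicate numbers do not pair the samples: over 27 pairs of the same number the mean correlation of deviations was -0.006, 6 of them were over 0.1, and 2 of 20 arrays went best with their own number. With the replicate block 0 features were called at 5.5 and at 45.6 mg/L, 295 at 90.4 mg/L, 0 in both comparisons of neighbouring concentrations and 77 for the trend.

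Some list medians changed sign. Without the 7 arrays these were circadian clock and ribosome biogenesis at 5.5 mg/L (0.018 and 0.343). The median of skeletal muscle at 5.5 mg/L was 0.002 with weights and 0.02 without the 2 arrays or replicate 2, and that of hypoxia at 90.4 mg/L -0.013 with every probe, while the tests kept their direction. At 45.6 mg/L the medians that turned were those of cell cycle (0.106 with weights, 0.003 without the 2 arrays, 0.014 without the 7, -0.382 to 0.003 on leaving out 1 array) and collagen, at 0.07 with weights, 0.058 without the 2 arrays and -0.48 to 0.058 on leaving out 1 array. For cholesterol at 45.6 mg/L only the direction of the test turned, and its median kept the sign (-0.049 with weights and -0.009 without the 7). On dim arrays fewer features can be measured: 16307 were above background on all 20, and 26212 entered with no filter.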

Other observations

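The tests of genes and lists were planned, and the shares by chromosome were looked at only after the results were seen.

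Some genes of lists that did not shift as a whole changed at 90.4 mg/L. ass1, which encodes argininosuccinate synthase of the arginine list, rose by 1.15 ± 0.25 (adjusted p = 0.0183, limma), and smox, a polyamine oxidase gene of the same list, fell by 0.89 ± 0.25 (adjusted p = 0.0473). In the ionocyte and ion transport list (33 measured, 2 higher, adjusted p = 0.0679) foxi3a, a regulator of ionocyte fate, rose by 0.91 ± 0.25 (adjusted p = 0.0451) beside trpv6. The death receptor gene fas of the p53 and DNA damage list fell by 0.81 ± 0.18 (adjusted p = 0.0192) and crfb4 of the innate immune list by 0.83 ± 0.23 (adjusted p = 0.0438). nr4a2b of the immediate early genes fell by 0.81 ± 0.18 (adjusted p = 0.0201) and the crystallin gene crybb3 by 0.81 ± 0.22 (adjusted p = 0.042). The zinc exporter gene slc30a1a rose by 0.43 ± 0.12 (adjusted p = 0.0415) and the chaperone gene pdia6 by 0.56 ± 0.16 (adjusted p = 0.0473). The hepatic lipase gene lipca rose by 0.96 ± 0.24 (adjusted p = 0.0311) and ihha, an Indian hedgehog gene, by 0.59 ± 0.13 (adjusted p = 0.0224). Of these, none was called in every fit that left out 1 array, and smox, foxi3a, fas, crfb4, crybb3, slc30a1a and lipca were not called with slide as a block (adjusted p from 0.0514 to 0.119).

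Members of the hypoxia, liver and glia and myelin lists also passed at 90.4 mg/L. These lists lay higher at adjusted p = 0.044, 0.0404 and 0.0345, but at p = 0.0895, 0.411 and 0.065 with an estimated correlation, and the hypoxia and liver lists not with slide as a block (adjusted p = 0.063 and 0.0754). With array row as a block the hypoxia list did not pass either (adjusted p = 0.0511). Of the 20 fits that left out 1 array, the hypoxia list was called in 14, the liver list in 16, the glia and myelin list in 18 and the heat shock list in 17. The oxygen sensor gene egln3 of the hypoxia list rose by 1.18 ± 0.29 (adjusted p = 0.0287). The tyrosine and methionine metabolism genes fah and cbsa of the liver list rose by 0.54 ± 0.13 and 0.57 ± 0.15 (adjusted p = 0.0316 and 0.0328), and the water channel gene aqp1a.1 of the glia and myelin list by 0.59 ± 0.13 (adjusted p = 0.0177). None of these 4 passed with slide as a block (adjusted p from 0.0507 to 0.0793). In the heat shock response list (25 measured, adjusted p = 0.0345, and p = 0.305 with an estimated correlation) no member passed, the list did not pass with array row as a block (adjusted p = 0.0692), and hsp70l had a log2 difference of 1.63 ± 0.67 (adjusted p = 0.155). Nor did cyp2k6 of the AhR and xenobiotic metabolism list, with 2.48 ± 0.88 (adjusted p = 0.102).

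By chromosome, the lower calls at 90.4 mg/L made up from 2% of the features tested on chromosome 2 to 6.7% on chromosome 22 (53 of 788), with 6% on chromosome 10 (44 of 739) and 5.7% on chromosome 4 (42 of 733). These shares were not tested.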
